A study of Homo sapiens with 5 samples.

How the data were processed

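RNA from JAR choriocarcinoma cells transfected with a miR-34a mimic (2 arrays) or a scrambled control (3 arrays) was hybridised to an Affymetrix whole-transcript array after amplification and biotin labelling, per the labels' protocols. The deposited values are log2 expression values, 1 per probeset and array, made by robust multi-array averaging (RMA) in Expression Console with core-exon analysis, per the labels. The submitters' processing notes also name Partek, with no version and no role. The values' range of 1.70 to 19.1 was that of a log2 scale, and the array medians over all probesets were 6.13, 6.13, 6.09, 6.14 and 6.16 for mimic 1, mimic 2 and controls 1, 2 and 3. Summarisation by RMA corrects background and normalizes the arrays together, so levels are relative within this set of arrays, and small differences of dim genes can be compressed. The annotation version behind the probesets is not given in the sources used here, and no genome build is named, so no coordinates are given.

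The table held 24351 probesets. The annotation gave 1 gene symbol for 17709 of them, several for 0 and none for 6642, of which 2197 were positive controls, 612 negative controls, 63 ERCC spike-ins, 23 background sets by GC content, 8 bacterial and phage spike-ins and 3739 others. All 17709 symbols either equalled the current RefSeq symbol or had no RefSeq entry and were kept as given, and the latter were not counted apart. Where a symbol had more than 1 probeset, as 20 symbols did, the brightest by mean over the 5 arrays was kept, which left 17687 genes. No filter on dim genes was applied in the reported test.

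Differences are mimic minus control on the log2 scale. They were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, no covariate), two-sided, with Benjamini-Hochberg adjustment over all genes and an adjusted p threshold of 0.05. The fit had 3 residual degrees of freedom and a prior of 3.67. Standard errors and 95% intervals are those of the moderated fit. Gene lists were tested with limma's camera with a preset inter-gene correlation of 0.01, adjusted over the 18 lists, and each list's members were also adjusted over the list alone. The lists were written from general knowledge before the data were examined. They covered reported miR-34a targets, p53 target genes, G1/S and DNA replication, G2/M and mitosis, 3 trophoblast lists, the Notch and Wnt/beta-catenin pathways, sterol and fatty acid synthesis, interferon-stimulated genes, glycolysis, hypoxia, the unfolded protein and ATF4 response, epithelial and mesenchymal genes, the RNA interference machinery, and markers of fibroblasts and of endothelial and blood cells. The test of genes with a miR-34a seed match in the 3' UTR was not run, because no transcript sequences were used here. A check of gene length was run and withdrawn, since no build is named: it showed a weak trend of longer genes to be higher in the mimic arrays, with the target, immediate-early and ciliary groups apart from lists matched on length and level, and it is not counted as evidence here.

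The genes named are MIR34A or its host gene where a probeset has that name, and up to 12 genes in each direction past the threshold whose groups did not overlap. If fewer than 6 passed, these were filled by smallest unadjusted p and are said to have missed the threshold. Genes of clone, noncoding, olfactory and immune-receptor symbol families were counted but not named. Up to 4 members of each list past the threshold, or otherwise the member of smallest p, and 15 fixed targets are also named. Other genes were chosen after their values were seen: FOSL1, TGIF2, ARHGAP1, CGB1, CGB3, CGB7, CGB8, CYP19A1, ERVFRD-1, TFAP2A, DLX3, HES1, HES2, HES4, HES5, HEY1, HEYL, MCM3, MCM5, CDT1, CDC25A, CDKN1A, ZMAT3, and those of the closing observations that are not given here.

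The alternatives planned before the data were examined were quantile normalization, subtraction of array medians, filters on dim genes (above the median or above 6), eBayes with trend and robust, array weights, the replicate number as a block, each array left out, the mean of a gene's probesets, other thresholds, every probeset, and an estimated inter-gene correlation. The trend and the robust setting on their own, and the averaging of the near-identical chorionic gonadotrophin beta genes into 1 gene, were added after the data were seen. With an array left out, a group of 1 array was assumed to vary like the other group. The tests were tested on simulated arrays in 20 runs, with the real genes' means and 200 changed genes. Each simulated gene's variance was drawn from the trended prior fitted to the real arrays, and genes were independent of each other. The runs therefore favoured a trended prior and cannot show how correlated genes affect the gene test or the list test. In these runs the default prior made a median of 0 calls with no changed gene and recovered 84% of genes changed by 1.5 log2 units. The list test detected a shift of -0.15 in a list of 56 genes in 100% of runs at an unadjusted p under 0.05, and gave such a p in 5% of runs with no shift; no adjustment over lists was simulated. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

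Signal over background was read from the control probesets. The share of positive-control probesets ranked above negative ones, as the area under the curve, was 0.974 to 0.980 per array. Between 6077 and 7576 genes (34.4% to 42.8%) lay above the 95th percentile of the negative controls of their array, and 10058 lay above it on no array, as did 40 of the 98 genes chosen for naming. The residual SD of a gene's log2 values had a median of 0.223 at mean values up to 4 and 0.0746 above 12. Array precision is limited by the number of arrays.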

Results

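Messenger RNA levels were measured by whole-transcript array in JAR cells, a human choriocarcinoma line with trophoblast features that makes placental hormones. The cells had been transfected either with a mimic of the microRNA miR-34a, a small RNA that p53 induces and that lowers mRNAs carrying matching sites, or with a scrambled control. The mimic group held 2 arrays and the control group 3. The values compared were log2 expression values for 17687 genes. The array medians over those genes lay between 5.94 and 6.0, and any pair of arrays correlated across genes, which are not independent replicates, with a Pearson r of 0.995 to 0.996. Genes called not above background here lay below the 95th percentile of the negative controls, 6.97 to 8.24, on every array, and the size of their differences is uncertain. Named genes without that remark were above it on some or all arrays. The number of arrays limits the precision: the median standard error of a log2 difference was 0.156. The labels do not say whether the arrays of a group came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical.

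The comparison of mimic with control asks which transcripts differ once miR-34a is added. Genes reported in the literature as miR-34a targets lay lower as a group in the mimic arrays (camera adjusted p 0.00127 with a preset inter-gene correlation, but adjusted p 0.285 with an estimated correlation). Of the 56 listed genes measured, 41 were lower and 15 higher, with a mean log2 difference of -0.12 and a median of -0.16, or -0.14 against all other genes. The cyclin-dependent kinase gene CDK4 was at a log2 value of 13.47 ± 0.07 (SD, n = 2) in the mimic arrays and 14.09 ± 0.05 (SD, n = 3) in the controls, a difference of -0.61 with a 95% interval of -0.90 to -0.33. The Rho GTPase-activating gene ARHGAP1 differed by -0.59 ± 0.13 (SE) and the homeobox repressor gene TGIF2 by -0.53 ± 0.12 (SE).

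The shift of the list was tested with limma's camera, which compares the listed genes with all others. With the preset inter-gene correlation the two-sided p was 7.05e-05 and the adjusted p 0.00127 over the 18 gene lists tested (Benjamini-Hochberg). The correlation estimated for the list was -0.0015, below the preset one. When the correlation is estimated, camera also refers its statistic to the 3 residual degrees of freedom, which it does not do with a preset one. The same test gave a p of 0.0159 and an adjusted p of 0.285 with this estimated correlation, so the call was lost there. It was also lost when either of 2 arrays was left out: the adjusted p was 0.0891 without miR-34a mimic 2 and 0.0533 without scrambled control 1. Against other genes the shift was -0.11 without mimic 2 and -0.12 without control 1, and -0.14 with all arrays. In scrambled control 1 the poly-A spike-in probesets were higher than in the other 4 arrays, for example 9.24 against 8.49 to 8.63 for dap. The bioB, bioC, bioD and cre spike-in probesets were higher in controls 1 and 2 than in the other arrays. For bioB the values were 8.31 and 8.17 against 7.69 to 7.77. No listed gene passed an adjusted p under 0.05 over all genes in limma with the default prior, where 11 lower and 3 higher members reached an unadjusted p under 0.05. Adjusted over the list alone, 5 members passed. CDK4, TGIF2 and ARHGAP1 fell. The AP-1 subunit gene FOSL1, in the lower direction, and the interleukin-6 receptor gene IL6R, in the higher, passed too but were not above background. FOSL1, TGIF2 and ARHGAP1 were named after their values were seen.

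**Figure D1:**
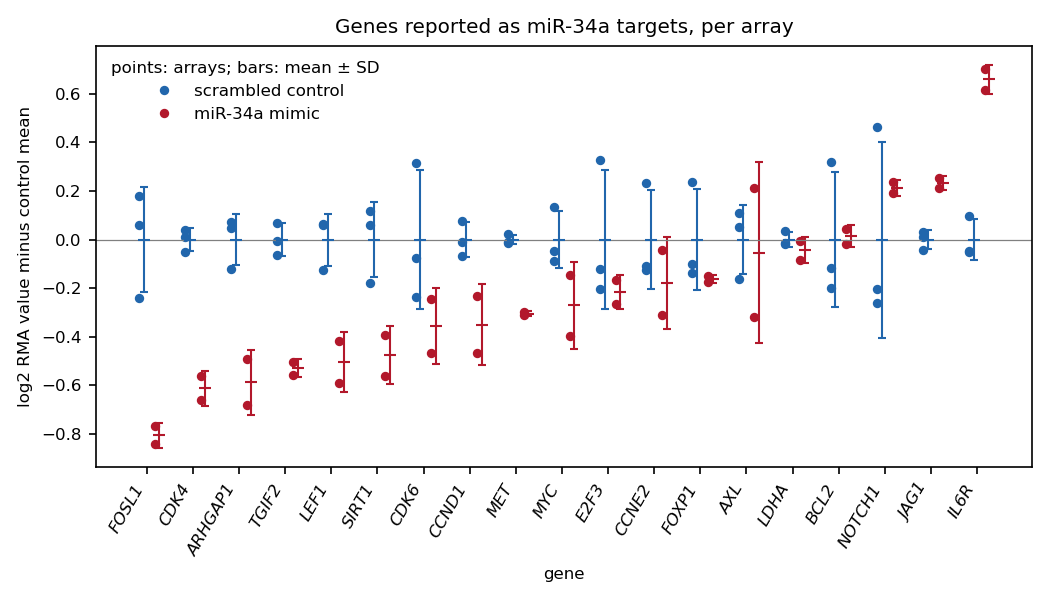
Log2 expression of 19 genes on the list of reported miR-34a targets, on each array relative to the mean of the control arrays (vertical axis, log2 units), ordered by the mimic minus control difference. Points are arrays, 2 with miR-34a mimic (red) and 3 with scrambled control (blue), and bars give the mean ± SD; both mimic arrays lie below all 3 controls for CDK4 (difference -0.61) and above them for IL6R, which was not above background.

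Among the 15 target genes fixed for naming, those with an unadjusted p under 0.05 were all lower in the mimic arrays, and none passed the adjusted p over all genes with limma's default prior. Beside CDK4 they were the Wnt-pathway transcription factor gene LEF1 at -0.50 ± 0.13 (SE), the NAD-dependent deacetylase gene SIRT1 at -0.48 ± 0.14, the cyclin D1 gene CCND1 at -0.35 ± 0.13 and the hepatocyte growth factor receptor gene MET at -0.30 ± 0.11; CCND1 came as near to 0 as -0.23 with 1 array left out. Differences of CDK6 (-0.36 ± 0.19), MYC (-0.27 ± 0.14), E2F3 (-0.22 ± 0.18), CCNE2 (-0.18 ± 0.17) and FOXP1 (-0.16 ± 0.15) had 95% intervals that included 0, and with 1 array left out they came as near to 0 as -0.20, -0.14, -0.053, -0.044 and -0.044. The same was true of AXL at -0.05 ± 0.19, LDHA at -0.04 ± 0.12 and BCL2 at 0.01 ± 0.18, and AXL and BCL2 changed sign when single arrays were left out, while LDHA came as near to 0 as -0.0052. LEF1, CDK6, BCL2, AXL, NOTCH1 and JAG1 were not above background. The Notch receptor gene NOTCH1 was at 0.21 ± 0.23 (down to 0.082 with 1 array left out) and its ligand gene JAG1 at 0.23 ± 0.12. The array carried 0 probesets named for MIR34A or its host gene, so delivery of the mimic could not be checked from these values.

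Over all 17687 genes the differences were small. They ran from -1.17 to 1.07 on the log2 scale, and 6 genes differed at least 2-fold. No gene passed an adjusted p under 0.05 in limma with its default variance prior (0 of 17687, smallest adjusted p 0.569, Benjamini-Hochberg). At an unadjusted p under 0.05 there were 1374 genes, 742 higher and 632 lower, where chance alone gives 884. The share that was higher, 54%, was not stable: it was 49.9% with quantile normalization and 48.9% to 57.6% with 1 array left out. The groups did not overlap in 26.9% of genes, against 20% by chance. With a variance prior that follows the signal level and is robust to outlying variances (limma, trend and robust), 42 genes passed the adjusted p, 33 lower and 9 higher. On simulated arrays the default prior recovered a median of 45% of genes changed by 1 log2 unit and 0% of those by 0.5. The trended and robust prior recovered 71% and 16%. The median number of false calls was 1.5 with the default prior and 7 with the trended and robust one. The simulated variances were drawn from the fitted trended prior, with independent genes, so these runs favoured that prior.

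Of the 42 genes that passed with the trended and robust prior, all had mean log2 values of 9.66 or more. EGR1, an immediate-early transcription factor gene, differed by -0.99 ± 0.16 (SE in the default fit), and CDK4 by -0.61 ± 0.12; both had an adjusted p of 0.00284 in that limma fit. The gene of the death ligand TRAIL, TNFSF10, differed by -0.71 ± 0.12, the vesicle-tethering gene TRAPPC1 by -0.65 ± 0.12, the retinol dehydrogenase gene RDH11 by -0.90 ± 0.17, RUSF1 by -0.87 ± 0.16 and the extracellular matrix gene NPNT by -0.74 ± 0.13. The haem oxygenase gene HMOX1 was among the 9 higher genes at 0.74 ± 0.13. With the default prior none of these passed.

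By the naming rule, the genes with the smallest unadjusted p in each direction are given although they missed the threshold. The lower ones outside the 42 were the zinc finger gene ZNF358 at -0.97, SNX29P2 at -0.93, the syndecan gene SDC1 at -0.90, the inhibitor of DNA binding gene ID3 at -0.90, the AP-1 subunit gene FOSB at -0.73 and the innate immune sensor gene NOD1 at -0.73. The higher ones were AKAP14 at 0.94, P2RY10 at 0.91, the synaptic gene SNAP25 at 0.86, SNX7 at 0.85, TMEM156 at 0.85, GLMN at 0.83, the intraflagellar transport gene IFT88 at 0.79, the alpha-globin gene HBA2 at 0.79, the double-stranded RNA sensor gene TLR3 at 0.76, the taste receptor gene TAS2R10 at 0.74 and ABCA9 at 0.70. The standard errors of the default fit for these genes lay between 0.12 for TLR3 and 0.17 for AKAP14. Apart from SDC1, ID3, FOSB and IFT88, these genes were not above background. SDC1 and IFT88 were above it on only 2 arrays, and ID3 and FOSB on 3. All had an adjusted p of 0.569 in limma.

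Genes of the syncytiotrophoblast and its hormones lay on average below the other genes in the mimic arrays, without passing the list test. Of 44 measured, 28 were lower and 16 higher, with a mean log2 difference of -0.09. All 6 measured genes of the chorionic gonadotrophin beta subunit were lower, with a mean of -0.46 ± 0.23 (SD over genes): CGB3 differed by -0.75 ± 0.20 (SE), CGB8 by -0.71 ± 0.13, CGB1 by -0.46 ± 0.16 and CGB7 by -0.41 ± 0.15. With 1 array left out CGB3 lay between -1.07 and -0.43 and CGB7 between -0.57 and -0.25. These genes are near-identical copies, so the probesets may not tell them apart, and they were singled out after their values were seen. In the other direction, the aromatase gene CYP19A1 was at 0.41 ± 0.12 and the fusogen gene ERVFRD-1, which encodes syncytin-2 and was not above background, at 0.40 ± 0.13. The camera p of the list was 0.0209 (adjusted p 0.126, and adjusted p 0.438 with an estimated correlation). Among genes with a mean log2 value above 6, the 18 listed genes that remained were lower than the rest by a mean of -0.20, and the adjusted p was 0.0143. That pass rested on the near-identical copies: the other 12 of the 18 had a mean of -0.047, or 0.031 without SDC1. With the 6 copies averaged into 1 gene, a setting added after the data were seen, the adjusted p was 0.422 among those genes and 0.688 among all genes. In limma with the default prior no listed gene passed over all genes, and SDC1 and CGB8 passed when adjusted over the list alone. CGB8 passed over all genes with the trended and robust prior (adjusted p 0.0447).

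Other trophoblast markers went both ways. Of 29 cytotrophoblast and trophoblast stem genes, 16 were lower and 13 higher, and the camera adjusted p was 0.524. SPINT1, which encodes a membrane protease inhibitor of the trophoblast, fell by 0.78 on the log2 scale when adjusted over the list alone, and passed over all genes with the trended and robust prior in limma (adjusted p 0.00925). DLX3 at -0.52 ± 0.19 (SE) and TFAP2A at -0.44 ± 0.16, both transcription factor genes, did not pass, and with 1 array left out they came as near to 0 as -0.30 and -0.23. Of 23 extravillous trophoblast and invasion genes, 14 were lower and 9 higher (adjusted p 0.704), and the sulfhydryl oxidase gene QSOX1 had the smallest p at -0.36 ± 0.13.

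The cell-cycle and p53 lists did not pass the list test. Of 52 genes of the G1/S transition and DNA replication, 27 were lower and 25 higher (camera adjusted p 0.524), and the 5 members with the smallest p were all lower. The thymidine kinase gene TK1 was at -0.97 ± 0.20 (SE), the licensing factor gene CDT1, not above background, at -0.71 ± 0.20, the phosphatase gene CDC25A at -0.62 ± 0.19, and the replicative helicase genes MCM5 and MCM3 at -0.50 ± 0.14 and -0.46 ± 0.13. None passed when adjusted over the list alone, and TK1 passed over all genes with the trended and robust prior in limma (adjusted p 0.0245). Of 45 genes of G2/M and mitosis, 20 were lower and 25 higher, with a mean of -0.01 and a median of 0.03 (adjusted p 0.704). The mitotic kinesin gene KIF20A was at -0.40 ± 0.12. Of 27 p53 target genes, 11 were lower and 16 higher (adjusted p 0.704). The ribonucleotide reductase gene RRM2B was at 0.51 ± 0.15 and ZMAT3 at 0.32 ± 0.12, and the cell-cycle inhibitor gene CDKN1A was at -0.56 ± 0.23, with overlapping groups and a range of -0.87 to -0.25 with 1 array left out.

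**Figure D2:**
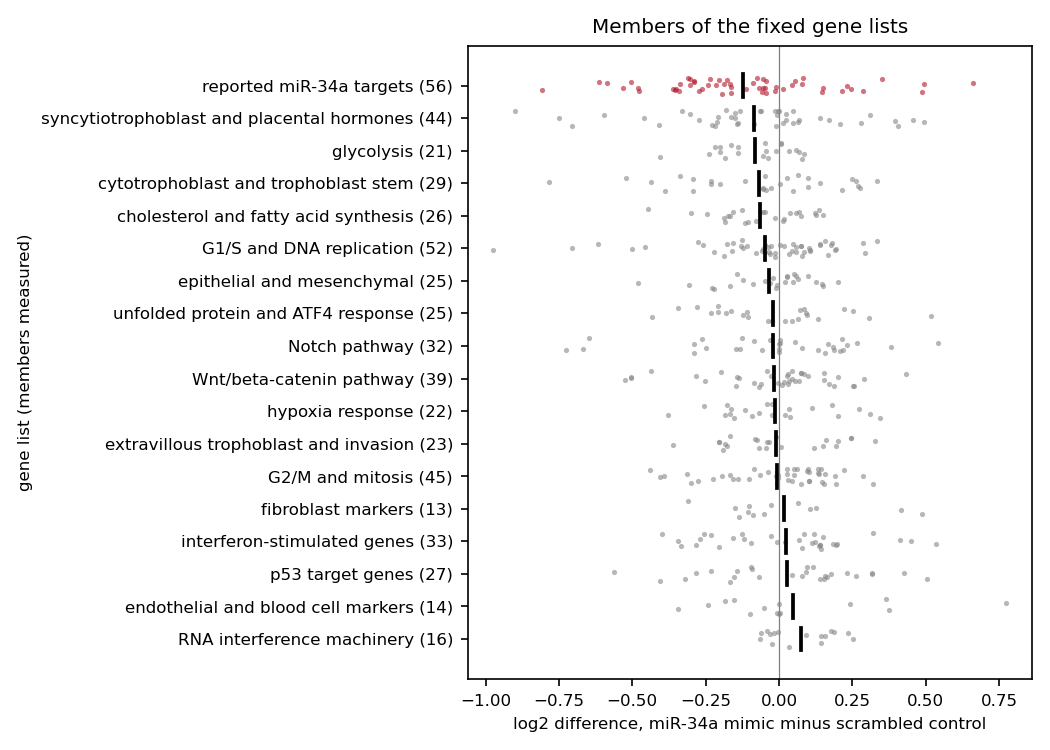
Log2 difference between miR-34a mimic and scrambled control (horizontal axis) for each measured member of the 18 gene lists, ordered by the mean difference, with the number of members in brackets. Points are genes, vertical bars are list means, and red marks the only list with a camera adjusted p under 0.05, the reported miR-34a targets with a mean of -0.12; with an estimated correlation its adjusted p was 0.285 and no list passed.

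In the Notch list, 14 of 32 genes were lower and 18 higher, with a mean of -0.02 and a median of 0.0018 (camera adjusted p 0.704). The effector gene HES1 fell when adjusted over the list alone, by 0.65 on the log2 scale; HEY2 passed in the same direction but was not above background, and HEY1 was at -0.67 ± 0.23 (SE). Other genes of these families were not lower to that extent, with HES4 at 0.18 (down to 0.085 with 1 array left out) and HES2, HES5 and HEYL, which were not above background, near 0. HES1, HEY1 and these 4 were picked out after their values were seen. In the Wnt/beta-catenin list, 16 of 39 genes were lower and 23 higher, with LEF1, not above background, the member of smallest p. Its mean of -0.02 and median of 0.03 differed in sign, and its adjusted p was 0.704.

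Of 21 glycolysis genes, 14 were lower and 7 higher, with a mean of -0.08. The camera p was 0.0133 (adjusted p 0.120, and adjusted p 0.438 with an estimated correlation), and with a trended prior the adjusted p was 0.0249. The enolase gene ENO2, which was not above background, had the smallest p at -0.41 ± 0.13 (SE). Of 26 cholesterol and fatty acid synthesis genes, 16 were lower and 10 higher (adjusted p 0.306), with the sterol reductase gene DHCR7 at -0.45 ± 0.12. In the hypoxia list 13 of 22 genes were lower, and the oxygen-sensing hydroxylase gene EGLN1 was at 0.34 ± 0.12. In the unfolded protein and ATF4 list 13 of 25 were lower, and the cystine transporter gene SLC7A11 was at 0.52 ± 0.16. In the epithelial and mesenchymal list 13 of 25 were lower, and SNAI1, a repressor of E-cadherin that was not above background, was at -0.48 ± 0.19, or -0.31 at the nearest to 0 with 1 array left out. The adjusted p of each of these 3 lists was 0.704.

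Interferon-stimulated genes, which can respond to transfected RNA, did not pass the list test: 14 of 33 were lower and 19 higher (camera adjusted p 0.992), with the helicase gene DDX60, not above background, at 0.45 ± 0.14 (SE). The mean of that list was 0.02 and its median 0.08, and the camera test ranked it slightly below other genes. Of 16 genes of the RNA interference machinery, 7 were lower and 9 higher (adjusted p 0.686), with the microRNA-processing nuclease gene DROSHA at 0.25 ± 0.14, or down to 0.16 with 1 array left out. Markers of other cell types did not pass it either. Of 13 fibroblast genes, 8 were lower and 5 higher (adjusted p 0.944), with a mean of 0.02 and a median of -0.05, and COL1A1, not above background, was at 0.42 ± 0.20, or down to 0.27 with 1 array left out. Of 14 endothelial and blood cell markers, 9 were lower and 5 higher (adjusted p 0.770), with a mean of 0.05 and a median just below 0. The alpha-globin gene HBA1 passed in the higher direction when adjusted over that list alone. HBA1 and HBA2 are near-identical copies and were not above background, with control means of 5.69 and 5.64.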

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

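The trend and robust settings on their own and the averaging of gonadotrophin copies were added after the data were seen. The count of genes past the adjusted p in limma was 0 in every alternative listed before the data were examined except 1, and genes at an unadjusted p under 0.05 numbered 1018 to 1406 in the alternatives that kept all genes and the default prior, array weights apart (1523). The exception was eBayes with trend and robust, with 42 genes; trend alone gave 43 and robust alone 0. The residual spread falls with signal level, and the calls came with the trended prior and not with the robust one. The list test took no robust setting, so there robust alone repeated the reported test, and trend and robust repeated trend alone. Each of the 2 filters on dim genes left 36 listed targets, with nearly the same p. The alternatives counted next are therefore not all separate. The reported miR-34a targets kept their direction in every alternative. Of the 15 alternatives with the preset correlation, 13 kept an adjusted p under 0.05, with a range of 9.13e-05 to 0.0891; leaving out arrays gave 0.000946 to 0.0891, with the call lost without miR-34a mimic 2 (0.0891) and without scrambled control 1 (0.0533). An estimated inter-gene correlation gave 0.285. The estimate for this list was -0.0015, below the preset value. A stronger correlation among the listed genes is therefore argued against as the reason for the larger p. With an estimated correlation, camera also refers its statistic to the 3 residual degrees of freedom, and with a preset one it does not. How much of the larger p comes from this was not tested. The number of lists past the adjusted p was 1 as reported. It was 2 with either filter on dim genes (the hormone list was added, but not with its 6 near-identical gonadotrophin copies as 1 gene, adjusted p 0.422) and with trend and robust or trend alone (glycolysis was added), 0 with an estimated correlation, and 0 to 1 with an array left out.

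The replicate number as a block left 0 genes past the adjusted p, 1081 at an unadjusted p, an adjusted p of 0.00631 for the reported targets and 1 list, and changed no call. Control 3 has no partner, so this fit is nearly that without it. The labels share only numbers: the deviations from the group means of same-numbered arrays correlated across genes at -0.0113 and -0.0354, and with only 2 such pairs the numbers were not taken to pair the arrays.

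Sign changes were seen for values near 0, and the cause was not tested. With the block, the mean shift against other genes was -0.027 for the interferon list and 0.018 for the fibroblast list. Array weights gave -0.028 for BCL2. With an array left out, the shifts ranged from -0.038 to 0.049 (interferon), -0.036 to 0.036 (fibroblast), -0.055 to 0.0022 (extravillous), -0.025 to 0.087 (endothelial and blood) and -0.034 to 0.033 (p53 targets), and the log2 differences from -0.088 to 0.17 (BCL2), -0.32 to 0.21 (AXL), -0.078 to 0.12 (HES2), -0.099 to 0.15 (HES5) and -0.36 to 0.36 (HEYL). The block gave 0.15 for HES5 and -0.013 for HEYL, and quantile normalization -0.0042 for HES2 and -0.016 for HEYL. HES2 was at -0.027 with array weights. Apart from these, 1345 values of named genes kept their direction and side of the threshold and 40 passed it with a trended prior. With an array left out, 17 of the 98 genes chosen for naming kept their sign but came at least 1.5 times nearer to 0. The seed-match alternatives were not run.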

Other observations

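The test of expressed against dim target genes was chosen only after the result was seen, the immediate-early and ciliary groups after their leading genes had been seen, and the single genes of this part after their values were seen. The 42 genes that passed the adjusted p with the trended and robust prior in limma were not tested for enrichment of any function. Among them, the cofilin gene CFL1 differed by -0.40 ± 0.13 (SE in the default fit), the profilin gene PFN1 by -0.38 ± 0.12 and the gamma-actin gene ACTG1 by -0.25 ± 0.12, while the actin monomer-binding gene TWF1 was higher at 0.49 ± 0.12. Lower genes also included the progranulin gene GRN at -0.69 ± 0.13, the mitochondrial creatine kinase gene CKMT1B at -0.53 ± 0.12 and LY6E at -0.42 ± 0.12. CKMT1B has a near-identical copy. Higher genes included the Golgi gene TMF1 at 0.66 ± 0.12 and the co-chaperone gene CHORDC1 at 0.56 ± 0.12. Of the 42, 1 (CDK4) was on the list of reported targets, which held 56 of the 17687 genes tested.

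Of the 10 splits of the 5 arrays into 2 and 3, which cannot give a share under 0.05, 1 split, the real one, had 42 such genes, and the highest of the others had 0. The real split had 1374 genes at an unadjusted p under 0.05, and the highest of the others 1119; 1 split, the real one, reached that count. In simulated arrays with no changed gene the trended and robust prior made a median of 0 calls. With 200 changed genes it made a median of 7 false calls and at most 15, against a median of 1.5 with the default prior. The simulated variances were drawn from the fitted trended prior, with independent genes. These runs therefore cannot tell whether that prior makes false calls on the real arrays.

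For the lower level of the reported targets, a general trend with signal level is argued against: 0% of 10000 random lists matched on mean expression had a mean as low as -0.12, and 95% of them lay between -0.04 and 0.08. The bioB, bioC, bioD and cre spike-in probesets were high in controls 1 and 2, and leaving out both together was not tested. Leaving out control 2 alone gave a camera adjusted p of 0.000946. Scrambled control 1, whose poly-A spike-in probesets were also high, remains open as a contributor. Without it the shift against other genes was -0.12 ± 0.042 (SE over members) in place of -0.14 ± 0.038 and the adjusted p 0.0533, with fewer arrays and a slightly smaller shift, and without miR-34a mimic 2 the shift was -0.11 ± 0.041 and the adjusted p 0.0891. Only 1 of the 10 splits, the real one, had a camera p as small as 7.05e-05, and the smallest of the others was 0.00029 (adjusted p 0.00522, with 2 lists past it against 1 in the real split) for controls 1 and 3, which lay above a rest that holds both mimic arrays; these splits are too few for a share under 0.05. A candidate explanation is a lower level of those listed mRNAs that the cells express. Members with a mean above 6 lay lower than dimmer ones by a difference of -0.085 (one-sided permutation p 0.146), which does not decide it. The cut of 6 lies below the background line of 6.97 to 8.24, so not all of these members need be expressed. This comparison cannot tell a direct effect of the mimic from an indirect one, and seed matches were not examined.

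EGR1, FOSB, JUND and FOSL1 were among the genes with the smallest p in the lower direction, at -0.99, -0.73 and -0.82 for the first 3, while FOSL1 was not above background. Immediate-early genes may have been lower as a group: 25 of 35 others were lower, with a mean of -0.16 ± 0.039 (SE over genes) and a camera p of 6.66e-05 (p 0.0716 with an estimated correlation), and the 32 on no fixed list, without MYC, KLF4 and ATF3, had a mean of -0.14 ± 0.041 and a camera p of 0.00082 (p 0.0973 with an estimated correlation). At an unadjusted p under 0.05, 7 of the 35 were lower, such as IER5 at -0.45, CCN1 at -0.39 and EGR3 at -0.37, and CCN2 was higher at 0.34 (EGR3 and CCN2 were not above background), while 0 passed when adjusted over the group alone. A single array setting the shift is argued against, since the mean with 1 array left out was -0.129 at the highest. Time to harvest, GC content and gene length, whose check was withdrawn, stay open, and MYC, KLF4 and FOSL1 are also reported targets. Of the 35 others, the 18 above background on no array had a mean of -0.061, and the 17 above it on some array -0.26.

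IFT88, IFT56, AKAP14, CFAP221 and SPAG17, genes of cilia and flagella, were among those with the smallest p in the higher direction, at 0.79, 1.00, 0.94, 0.59 and 0.70, and all but IFT88 were not above background. Of 125 other ciliary genes, 87 were higher and 38 lower, with a mean of 0.13 ± 0.023 (SE over genes) and a camera p of 0.000788 (p 0.0351 with an estimated correlation), consistent with a higher level of the group. At an unadjusted p under 0.05, 19 of them were higher, such as CFAP43 at 0.46 and SPEF2 at 0.44, and 1 was lower (CFAP43 and SPEF2 were not above background), while 0 passed when adjusted over the group alone. A shift shared by genes of the same signal level is argued against: 0% of the matched random lists were as high. The group was dim, with a median mean log2 value of 4.99 and 91 of the 125 above background on no array. Those 91 had a mean difference of 0.096, and the 34 above background on some array had a mean of 0.24. GC content and gene length, whose check was withdrawn, stay open.

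Of the 23 background sets by GC content, the set with 3 GC bases had the largest difference, a mean of 0.625 higher in the mimic arrays, but the groups overlapped, at 6.82 and 7.46 against 6.01, 6.37 and 7.17. The other sets differed by -0.0835 to 0.17, and 11 of them were lower in the mimic arrays. The signs were ordered by GC content: sets with 8 to 18 GC bases were lower, and those with 4 to 7 or 19 to 25 were higher. Many of these differences were small, such as -0.0028 with 8 GC bases and 0.0057 with 22. In the sets with 6, 7, 22 and 23 GC bases scrambled control 1 was the lowest array, and another control lay above both mimic arrays. The order of signs may therefore depend on control 1. Whether GC content bears on the differences of dim genes was not tested. Of the 3739 probesets without a gene here, 0 passed the adjusted p in limma and 206 had an unadjusted p under 0.05.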
